A study of Mus musculus with 4 samples.

How the data were processed

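Splenic and lymph node cells of 2 wild-type C57/BL6 mice were measured by CITE-seq, an assay that counts messenger RNA and antibody-linked DNA tags in the same single cells. Per the labels, cells of each mouse were stained with a panel of 111 antibodies or with a panel of 208, so that 4 libraries fall into 2 groups (panel 111 and panel 208) of 2 libraries each. The replicate number in the labels is the mouse. Per the labels' protocols the mice were processed on separate days, so the animal and the day cannot be told apart. Per the same protocols, cells of the 2 organs carried different hashtag antibodies, which mark the origin of a cell, and were mixed before they went onto a 10x Chromium 3' v3 lane.

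The deposited matrices held whole-number UMI counts (unique molecular identifiers, 1 per captured molecule) per gene, antibody and cell, made by the authors with Cell Ranger 3.1.0 and the mm10 mouse genome, per the submitters' processing notes. The filtered matrices listed 39875 cells, 28692 genes, 208 antibodies with 9 isotype controls among them, and 2 hashtags. Strand handling and the rules for reads that match several genes were not given in the sources used here, so paralogs and overlapping genes are named with that limit. A second set of deposited count matrices combined the libraries of each panel, with software version 3.0.2 in place of 3.1.0, per the file headers. In these, 0 cells differed in total UMIs from the single-library matrices, so the authors had not evened out the depth. For 1 library (panel 111, mouse 2) an unfiltered matrix of all barcodes was also used. No cell type annotation was used, and no genome sequence was at hand, so no coordinates are given.

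Total RNA counts per library were 57757488 (panel 111, mouse 1), 56960371 (panel 208, mouse 1), 22989994 (panel 111, mouse 2) and 23281099 (panel 208, mouse 2). Median UMIs per cell were 4392, 4561, 2121 and 2102 in the same order. Cells were kept with at least 200 genes and at most 15% mitochondrial UMIs, which removed 2256 cells. Scrublet, run per library at the default settings of scanpy 1.11.5, then removed 1357 doublets (3.61%, 3.55%, 3.29% and 3.98% of the cells that passed). It marked 36.4% of the 1718 deposited cells that carried both hashtags, against 1.84% of cells with 1 hashtag. The remaining 36262 cells were analysed. A hashtag was assigned when it had at least 20 UMIs and at least 5 times those of the other hashtag.

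Counts were scaled to 10000 per cell and log-transformed, and 2000 highly variable genes were chosen per library among genes outside the readout lists. Ribosomal, mitochondrial, haemoglobin and immunoglobulin variable genes were left out of that choice. Values were centred and scaled within each library, reduced to 30 principal components, joined to 15 nearest neighbours and grouped by the Leiden method at resolution 1.5 (leidenalg 0.10.2, Python 3.11.15, seed 7), giving 32 clusters. Clusters were named "X-like" from 24 lists of marker genes, each with at least 3 detected markers, and 22 classes received a name. In the text the class names are shortened (a "CD4 T class" is CD4 T-like). The 2 unnamed clusters (14 and 30) were left out of tests by class.

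Raw counts were summed per library, or per class and mouse with both panels added, since cells are not replicates. Sums were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at a false discovery rate of 0.05. All tests were two-sided. Panels were compared without a term for mouse over the 4 whole libraries and within 19 classes with at least 20 cells in each library. Class contrasts used 1 fit over 22 classes with mouse as a term. Of 6 planned contrasts 5 were run. The sixth, between monocytes high and low in Ly6c2, was left out because monocytes formed 1 cluster. Genes used for clustering or naming were kept out of the contrasts, since they define the classes. The genes tested there are not independent of the classes either, since they vary along with the genes that define them. Cells with 1 hashtag were compared between hashtags within each class, with mouse as a term, where both hashtags had at least 20 cells in each library. Mice were compared as ratios of CPM, counts scaled by the library total, without a test, since each side has 1 animal. In the panel comparison without a term for mouse, p-values measure the spread between these 2 animals and run days. A term for mouse takes out the mean difference between the animals. In the class contrasts p-values therefore measure how far classes deviated between the 2 mice, a spread shared over all 22 classes.

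The genes were grouped in 13 readout lists of 303 genes: chemokine and egress receptors, integrins and adhesion, cytokine and TNF-family receptors, pattern recognition, MHC class II presentation, type I interferon response, Fc receptors, immediate-early and dissociation stress, antigen-receptor signalling, T-cell and NK regulators, B-cell and myeloid regulators, sex-linked genes, and RNA quality (nuclear and mitochondrial transcripts). Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with an estimated correlation. Named genes were chosen by rule. In the class contrasts these were up to 3 members per list that passed the test, had at least 20 CPM in 1 of the 2 classes and had the largest fold changes, then 3 higher and 3 lower genes outside the lists. In the panel comparison they were the 2 members per list with the smallest p and up to 10 called genes per direction. Predicted genes and variable segments of antigen receptors were counted but not named. Fold changes carry the standard error (SE) of the fit. A gene with 0 counts in 1 class is given as a lower bound against a floor of 3 counts over both mice, and one with 1 to 3 counts as a ratio of summed counts with an exact 95% interval. Intervals of shares are exact Clopper-Pearson 95% intervals, and both kinds cover counting error only.

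The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. Alternatives were DESeq2 1.42.0 (size factors alone, and its Wald test), no filter on low counts, the term for mouse added or removed, each library or mouse left out, doublets kept, 10% mitochondrial UMIs, counts thinned to equal depth, the combined matrices, sums per library, the 2 classes of a contrast alone, Leiden resolution 1.0 and no centring by library. Fits with a mouse left out, and class contrasts on the 2 classes alone, used sums per library with library as a term. With a mouse left out the units are 2 stainings of the same animal, so these fits do not measure spread between animals. Hashtag comparisons within each panel, a hashtag minimum of 50 UMIs, omission of cells with both hashtags or of cluster 14, tests of marker lists between panels, all antibody tests, and all tests of explanations were chosen after the data had been seen.

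The numbers pair the libraries because panel 111 and panel 208 of 1 number hold cells of the same mouse, per the labels. Deviations from the panel means were correlated between same-numbered libraries (r = 0.800 across genes, which are not independent), and the first principal component, with 82.8% of the variance, separated the mice. A chi-square test of the counts per degree of freedom gave 281 (panel 111) and 263 (panel 208) between mice, against 5.43 and 4.61 between the panels within mouse 1 and mouse 2. None of these 4 pairs agreed within sampling noise.

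The tests were tested on simulated data drawn from the means and depths of these libraries, with 200 genes changed. Between whole libraries, the test without mouse recovered 0 of 67 genes changed 1.5-fold, 1 of 64 changed 2-fold and 0 of 65 changed 4-fold. With mouse as a term it recovered 51 of 67, 56 of 66 and 65 of 65. Within classes, the test without mouse recovered 29.0% of 4-fold changes in CD4 T, 36.4% in other B and 77.0% in macrophage cells. In the class contrasts, 77.3% of 2-fold changes were recovered for CD8 over CD4 T cells, 68.2% for regulatory over CD4 T cells, 71.2% for marginal zone over other B cells, 30.3% for conventional DC1 over DC2 and 37.9% for NK over CD8 T cells. Unchanged genes made up 5.63% to 9.15% of the calls in these contrasts.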

Results

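RNA and surface proteins were measured together in single cells of the spleen and lymph nodes of 2 wild-type mice aged 5 weeks, with cells of each mouse stained with a panel of 111 or of 208 antibodies. The series title names joint modelling of both kinds of measurement as the purpose. The 4 libraries held 11160 cells (panel 111, mouse 1), 10777 (panel 208, mouse 1), 9017 (panel 111, mouse 2) and 8921 (panel 208, mouse 2), with a median of 1615, 1649, 926 and 937 genes per cell. Mouse 1 was sequenced to 57757488 and 56960371 UMIs and mouse 2 to 22989994 and 23281099, so values of rare transcripts rest on fewer counts in mouse 2. Antibodies shared by both panels gave a median of 2619, 2167, 3209 and 1567 UMIs per cell in the same order.

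B cells were the most abundant lymphocytes and T cells came next. Other B cells joined clusters 2, 3, 6, 8 and 13, which carried Cd79a, Cd79b and Pax5 and were given no narrower name. Cluster 8 was led by Il4i1 and Cd83, and cluster 6 had the marginal zone marker Cr2 among its top genes. The class made up 30.96% ± 5.44 of the cells (SD, 4 libraries). CD4 T cells followed with 18.03% ± 1.79 and CD8 T cells with 14.3% ± 1.85. Transitional B cells, recent immigrants marked by Vpreb3 and Cd93, held 6.76% ± 1.17, and marginal zone B cells (Cr2, Dtx1, Myof, S1pr3) held 4.13% ± 0.162. Regulatory T cells, defined by Foxp3 and Il2ra, took 2.75% ± 0.0392 and gamma-delta or innate-like T cells (Trdc) 2.37% ± 0.171. Among myeloid cells, macrophages (C1qa, Vcam1, Slc40a1) made up 2.28% ± 0.348, monocytes 1.18% ± 0.0231, conventional DC2 1.06% ± 0.181, neutrophils 0.860% ± 0.432, mature DC (Fscn1, Ccl22) 0.758% ± 0.0499 and conventional DC1 (Xcr1, Clec9a) 0.484% ± 0.0864. NK cells (Ncr1, Gzma) took 0.982% ± 0.109. B and T clusters led by interferon-induced genes such as Ifit3 held 1.60% ± 0.368 and 1.27% ± 0.370. A B-cell cluster led by Pxdc1 and Lmo2 held 5.69% ± 3.35, with means of 8.59% in mouse 1 and 2.79% in mouse 2. Neutrophils averaged 0.490% in mouse 1 and 1.23% in mouse 2, and erythroid cells 0.610% and 0.253%. Each of these differences was seen with both panels, but with 1 animal on each side none was tested. Several shares depended on the setting. At Leiden resolution 1.0 no class of conventional DC1, conventional DC2 or interferon-high T was found, monocytes held 2.19%, mature DC 1.24% and erythroid cells 0.308% in mouse 1 and 0.0841% in mouse 2. With doublets kept, gamma-delta or innate-like T cells held 4.13%, the interferon-high T class 1.94%, erythroid cells 0.314% and 0.0291% and the cluster led by Pxdc1 10.5% and 4.83%. The unnamed cluster 14 held 2.07% ± 3.99, and 676 of its 695 cells lay in the library of panel 208 and mouse 2. They count in the total of that library, which lowers the shares of its other classes. Different clusters supplied the CD4 T class, since 87.3% of it came from cluster 0 in mouse 1 and 81.7% from cluster 4 in mouse 2. The largest parts of the other B class were cluster 3 in mouse 1 (41.5%) and cluster 2 in mouse 2 (38.9%).

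**Figure D1:**
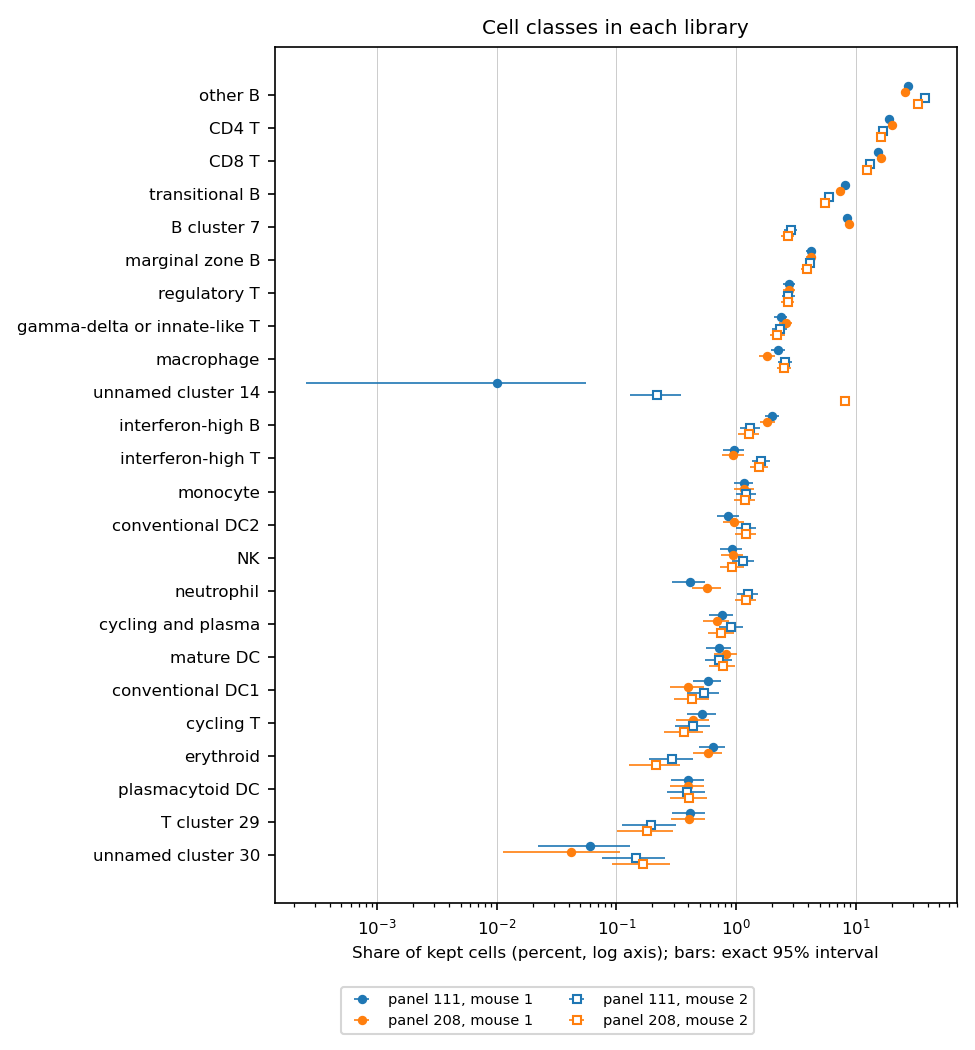
Share of kept cells in each class, in percent on a log axis, for the 4 libraries; bars are exact 95% intervals of counting error, and a class with 0 cells in a library (cluster 14 in panel 208, mouse 1) is not drawn. Most classes lie close together in all libraries, while cluster 14 reaches 8.06% in panel 208 of mouse 2.

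The organ of a cell is known only through its hashtag, and the 2 hashtag names fell on opposite cell types in the 2 panels. Marginal zone B cells, which reside in the spleen, carried the hashtag named spleen in 90.9% of cells (95% interval 87.7% to 93.6%) of mouse 1 and 95.6% (92.7% to 97.6%) of mouse 2 with panel 208. With panel 111 the same class carried it in 8.35% (5.85% to 11.5%) and 7.17% (4.60% to 10.6%). Transitional B cells showed 96.2% and 94.7% with panel 208, against 2.77% and 3.79% with panel 111. Monocytes ran from 94.3% and 91.1% to 9.82% and 5.38%, and NK cells from 78.0% and 85.3% to 22.5% and 16.7%. In mouse 2 alone, neutrophils with the hashtag named spleen were 97.8% with panel 208 and 0 of 90 cells with panel 111, which allows up to 4.02% there. CD4 and CD8 T cells went the other way, while gamma-delta or innate-like T cells ran from 56.1% and 60.6% with panel 208 to 40.2% and 31.1% with panel 111. CD4 T cells carried the hashtag named spleen in 25.9% (23.9% to 27.9%) and 39.0% (36.4% to 41.7%) of cells with panel 208, and in 74.1% (72.0% to 76.1%) and 63.7% (61.1% to 66.2%) with panel 111. Mature DC were at 8.33% and 11.1% with panel 208 and at 73.1% and 86.2% with panel 111. Of the 20 classes with at least 20 such cells in each library, 19 lay on opposite sides of their library's average in the 2 panels and on the same side in both mice. The exception was the plasmacytoid DC class, and 0 classes were on the same side in all libraries. The mean difference between panels was 52.1 percentage points, while the mice differed by 7.99 points within panel 111 and by 6.65 within panel 208. The median count of the stronger hashtag was 140, 126, 168 and 144 UMIs per cell in the order of the libraries above, and that of the weaker hashtag 1.

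**Figure D2:**
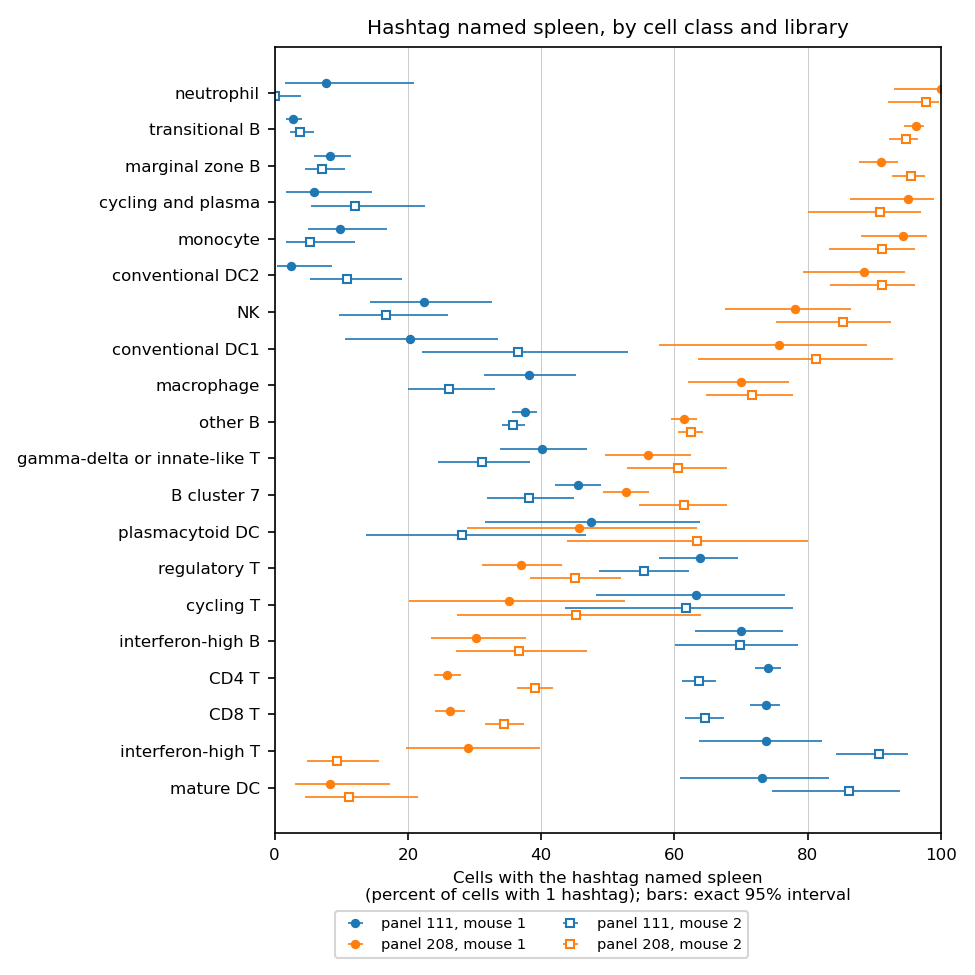
Share of cells that carry the hashtag named spleen, in percent of cells with 1 hashtag, by class and library; bars are exact 95% intervals of counting error. Marginal zone and transitional B cells lie above 90% with panel 208 and below 10% with panel 111, and CD4 and CD8 T cells show the reverse order.

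Genes within a class also moved in opposite directions between hashtags in the 2 panels, so no direction between organs is drawn from the pooled comparison. In other B cells of panel 208, those with the hashtag named spleen had more Fosb (log2 fold change 3.497 ± 0.32 SE), Fos (2.70 ± 0.31) and Cd69 (1.1005 ± 0.11), an early activation marker. In panel 111 the same genes were lower, at −3.80 ± 0.33, −2.43 ± 0.28 and −1.07 ± 0.10. Plac8 changed from 1.26 ± 0.05 to −1.17 ± 0.05, and Fcer2a (CD23) from −0.45 ± 0.04 to 0.44 ± 0.04. Ciita, the main activator of MHC class II genes, ran from −0.43 to 0.45, and H2-Eb2 from −0.52 to 0.47. CD4 T cells showed Klf3 at 0.86 ± 0.08 and −0.88 ± 0.08, Pim1 at 1.09 ± 0.12 and −1.41 ± 0.13, Junb at 0.80 ± 0.09 and −0.96 ± 0.09, and Il7r at 0.47 ± 0.06 and −0.39 ± 0.06. S1pr1, the receptor for egress from lymphoid organs, was at 0.26 ± 0.06 and −0.35 ± 0.06, and Mir142hg at −1.56 ± 0.09 and 1.44 ± 0.10. Haemoglobin Hbb-bs, a red-cell transcript whose near-identical copies share reads, differed in CD4 T cells of mouse 1 alone. With panel 111 it was at 23.2 CPM (counts scaled to the total of these cells) under the name spleen and 485 under the other, against 61.2 and 57.3 in mouse 2. The CD8 T class joins clusters 1 and 9, of which cluster 9 alone had Ccl5 as a detected marker. Different mixtures of these clusters under the hashtags are not excluded. The same limit holds for the clusters joined in the other B class (2, 3, 6, 8 and 13) and in the CD4 T class (0 and 4). In CD8 T cells Ccl5 was at 0.92 ± 0.07 and −1.28 ± 0.07 and Cxcr6 at −0.81 ± 0.12 and 0.84 ± 0.12. The chemokine gene Ccl4 was an exception, lower with that name in both panels (−2.78 ± 0.39 and −2.49 ± 0.36; edgeR interaction adjusted p = 0.90). With panel 208 that value came from mouse 1 (3.03 against 28.3 CPM), since mouse 2 had 2.67 against 1.46. These genes were chosen after their values were seen.

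With both panels added, edgeR called 33 of 60170 tests over 7 classes (9 higher and 24 lower with the hashtag named spleen). Within the panels the counts were 953 (526 higher, 427 lower) for panel 208 and 1043 (463 higher, 580 lower) for panel 111, each of 51572 tests. Of the 566 tests called in both panels, 563 had opposite signs, and 2675 tests passed the edgeR test of the difference between panels. Macrophages supplied 279 of the 566 and 1184 of the 2675. That class joins clusters 16 and 21, of which 1.75% and 85.2% carried the name spleen with panel 111 in mouse 1, so its values compare different mixtures of cells. The pooled count was 0 without the term for mouse (175 at an unadjusted p under 0.05), 1 by DESeq2, 7 without mouse 1 and 6 without mouse 2.

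RNA of libraries stained with panel 208 and with panel 111 differed in 0 of 13906 genes by edgeR without a term for mouse (13 at an unadjusted p under 0.05; n = 2 per panel), and in 52 with it. DESeq2 without that term called 0. The Fc receptor list had 0 of 12 members called, with Fcgr3 at a log2 fold change of 0.20. All 13 readout lists had 0 members called over all genes and 0 adjusted over the list alone, and camera called 0 lists (adjusted p from 0.961 to 0.995, and 0.995 with an estimated correlation). Among the members with the smallest p were the chemokine receptors Ccr10 (−1.003 ± 0.43) and Ccr4 (−0.34), Klrg1 (−0.97 ± 0.38) and Ccl3 (−1.01 ± 0.63). Further values were 0.57 for Cd80, 0.20 for the interferon-induced Ifit3b, 0.57 for the heat-shock gene Hspa1b, −0.41 for Tlr9, −0.40 for Cd14, −0.47 for Kit, −0.06 for Xist and −0.13 for mt-Nd3. None of these passed edgeR (adjusted p = 1.00 for each). Simulated 4-fold changes were recovered by this fit for 0 of 65 genes, so changes of that size between panels were not detectable by it.

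With mouse as a term, which pairs the libraries of each animal, the 52 genes called were 41 higher and 11 lower with panel 208. Higher genes included those of mature DC, such as Ccl22 (0.75), a chemokine that attracts T cells, Cxcl16 (0.57), Apol7c (0.49) and Cacnb3 (0.45). Neutrophil genes were among them, with Ly6g at 1.26 ± 0.25, Stfa2l1 at 0.92 ± 0.18 and Retnlg at 0.73. The share of mature DC was higher with panel 208 in both mice (0.821% against 0.717% in mouse 1 and 0.775% against 0.719% in mouse 2). At Leiden resolution 1.0 it was lower (1.22% against 1.29% and 1.19% against 1.24%). No conventional DC1 class was found there, so the mature DC class may include those cells. In the main setting conventional DC1 were fewer with panel 208 (38 against 58 cells and 36 against 44). The share of neutrophils had no fixed direction. Neutrophils held 0.572% against 0.408% in mouse 1 and 1.20% against 1.25% in mouse 2. The largest positive values of the fit were those of Ighg2c (8.14 ± 0.30), an immunoglobulin constant gene, Ctsg (4.01 ± 0.64), Gzmc (2.95 ± 0.22) and Cd70 (2.90 ± 0.60). Lower genes included the stromal collagen gene Col1a2 (−2.35 ± 0.52), the matrix gene Dcn (−2.94 ± 0.47), Saa3 (−3.91 ± 0.51), Ccl3 (−1.02 ± 0.20) and Ikzf2 (−0.30 ± 0.05). In 7 of the 52 genes the 2 mice had opposite signs, among them Ighg2c (11.21 in mouse 1 and −1.099 in mouse 2), Saa3 (−6.13 and 2.17) and Retnlg (1.49 and −0.01). Single cells carried several of these values. The highest cell held 97.6% of the UMIs of Ighg2c, 88.3% of those of Saa3, 81.3% for Gzmc and 80% for Dcn, and 20 of the 52 genes had over 10% in 1 cell. Other called genes were spread over many cells and classes. Rps27rt had UMIs in 15703 cells (0.51 in mouse 1 and 0.30 in mouse 2, 0.044% in the highest cell). Wdr89 had them in 12464 cells (0.40 and 0.32, 0.069%). Rare cells therefore do not carry all 52 calls. For 22 of the 52 genes the highest cell was a mature DC, and 5 of the 6 markers of that class were called. Tested without mouse, the 24 marker lists gave 6 calls by camera. Mature DC (adjusted p = 5.47e-11), conventional DC2 (1.42e-06), neutrophil (0.00214), platelet (0.00258) and gamma-delta T markers (0.0431) were higher with panel 208, and stromal markers lower (0.00214). With an estimated correlation 0 lists were called, the lowest adjusted p being 0.561. Leaving out the panel 208 library of mouse 2 gave 1 gene, Ighg2c, without the term for mouse.

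Within 19 classes edgeR called 0 of 133090 tests between panels (650 at an unadjusted p under 0.05), and DESeq2 called 0. The term for mouse gave 135 calls (77 higher, 58 lower), and no filter on low counts gave 83 (47 higher, 36 lower). Without 1 library, where the lone library of its panel is assumed to vary like the other panel, the counts were 39 and 53 without panel 111 of mouse 1 and mouse 2, and 38 and 62 without panel 208 of mouse 1 and mouse 2.

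Single cytotoxic and homing genes were among the largest differences between CD8 and CD4 T cells. The CD8 T class joins clusters 1 and 9. Cluster 9, with Eomes, Nkg7 and Cxcr3 among its top genes, held 34.8% of it in mouse 1 and 19.8% in mouse 2. Values of the class average over both clusters and need not hold for each. The cytotoxic granule gene Nkg7 was 6.28 ± 0.34 higher (log2 fold change ± SE, n = 2 mice) and Eomes, a transcription factor of effector and memory cells, 4.33 ± 0.28. The receptor genes Cxcr6 (5.00 ± 0.30), Cxcr3 (4.99 ± 0.28), which binds interferon-induced chemokines, and Ccr9 (3.40 ± 0.21), a receptor for homing to the gut, were higher as well. Itgae, the chain of CD103 that binds E-cadherin, was 4.88 ± 0.26 higher, while Itgb3 was lower (−2.72 ± 0.15). In all, 932 of 9712 genes passed edgeR, 515 higher and 417 lower (1865 at an unadjusted p under 0.05). Chemokine and egress receptors had 7 of 24 members higher and 2 lower (7 and 3 adjusted over the list alone), and integrins and adhesion 6 and 3 of 29 (8 and 3). Cytokine and TNF-family receptors split into 8 higher and 7 lower of 38 (9 and 9), with Il2rb, the chain shared by IL-2 and IL-15 receptors, at 3.91 ± 0.24, and with Tgfbr3 (−1.53 ± 0.15) and the costimulatory Cd28 (−1.15 ± 0.18) lower. T-cell and NK regulators had 11 higher and 6 lower of 27 (11 and 7), with Ly6c1 at −4.86 ± 0.26, a value open to reads shared with its paralog Ly6c2. The sensors Nod1 (1.30 ± 0.18) and Aim2 (0.54 ± 0.15) were among 3 higher pattern recognition genes of 26 (4 adjusted over the list alone). MHC class II presentation had 3 of 14 higher (3), including H2-Oa (1.82 ± 0.18) and H2-DMa (0.69 ± 0.20). The antigen-receptor list had 5 of 22 higher (5, with 1 lower), including Traf1 (1.03 ± 0.14). Interferon genes were mixed, with Oas3 higher (1.39 ± 0.19) and Ifit2 lower (−0.89 ± 0.16) among 3 and 2 of 26 (3 and 3), and immediate-early genes had 3 and 2 of 27 (5 and 7). B-cell and myeloid regulators had 3 higher and 1 lower of 26 (3 and 1), including Plac8 (3.90 ± 0.34) and Cd72 (1.498 ± 0.18). Fc receptors had 1 of 13 higher (1), and the sex-linked (2 genes) and RNA quality lists (15) had 0. Outside the lists, Samd3 (6.72 ± 0.35, edgeR adjusted p = 1.79e-17), Adgrg5 (5.00 ± 0.30) and Lcn4 (4.24 ± 0.34) were highest, and Myo10 (−3.90 ± 0.28), Igsf23 (−2.37 ± 0.25) and the BMP9 receptor Acvrl1 (−2.03 ± 0.27) lowest. Camera called 0 of 13 lists, the smallest adjusted p being 0.0629 for T-cell and NK regulators (0.737 with an estimated correlation). The weakest named call was Myc (0.48 ± 0.15, edgeR adjusted p = 0.0314), and all named genes moved the same way in both mice. Without the term for mouse 124 genes passed. Without mouse 2 there were 1850, and without mouse 1 there were 496, with Aim2, Rilpl2 (0.75 ± 0.18) and Hsph1 (0.58 ± 0.13) no longer called. Each fit without a mouse had the 2 libraries of 1 animal as units, so it shows no spread between animals.

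Regulatory T cells carried more RNA of genes induced by antigen-receptor signals than CD4 T cells. Of 22 such genes 17 were higher and 0 lower (20 adjusted over the list alone), among them Cd83 (4.22 ± 0.41), the transcription factor Irf4 (2.94 ± 0.36) and Gadd45b (2.78 ± 0.39). The inhibitory receptors Lag3 (5.48 ± 0.52) and Pdcd1 (3.68 ± 0.35) were higher, and Klrg1 was 239-fold higher (95% counting interval 79.9 to 1178) over 3 UMIs in CD4 T cells. The tissue homing receptors Ccr6 (5.71 ± 0.41), Ccr4 (5.10 ± 0.37) and Cxcr3 (4.76 ± 0.35) were higher too. Chemokine and egress receptors had 9 of 24 members higher and 3 lower (11 and 3 adjusted over the list alone). Integrins and adhesion had 11 and 2 of 29 (12 and 2), including Itgae (3.87 ± 0.36), Itgb1 (3.22 ± 0.14) and Icam1 (1.85 ± 0.26). Cytokine and TNF-family receptors had 16 and 8 of 38 (17 and 10), with Il2rb (5.07 ± 0.25) and Tnfrsf9, also called 4-1BB (4.55 ± 0.24), higher and Tgfbr3 (−2.72 ± 0.27) lower. T-cell and NK regulators had 15 and 6 of 27 (16 and 7). B-cell and myeloid regulators had 6 and 2 of 26 (8 and 3), with Maf at 5.32 ± 0.18 (edgeR adjusted p = 4.11e-24), Irf8 at 1.75 ± 0.28 and Notch2 at 1.05 ± 0.21. Pattern recognition genes had 7 and 1 of 26 (7 and 1), with Nod1 (1.45 ± 0.26) and Tlr1 (0.73 ± 0.15). Camera called 11 of 13 lists, and 7 held with an estimated correlation, the antigen-receptor list at adjusted p = 5.51e-21 (2.62e-04 with an estimated correlation). The other calls that held were those of chemokine receptors (0.00911), integrins (0.00109), cytokine receptors (0.0129), pattern recognition (0.0358), T-cell and NK regulators (0.0358) and B-cell and myeloid regulators (0.0217), each given with an estimated correlation. Immediate-early genes had 7 of 27 higher (8), with Nr4a3 (2.26 ± 0.39) and Nr4a1 (1.55 ± 0.25), and the call was lost (adjusted p = 0.0696 with an estimated correlation). Interferon genes had 5 and 2 of 26 (7 and 2), with Ifit3 at 1.28 ± 0.40 (edgeR adjusted p = 0.0271) and Isg20 at 1.08 ± 0.27, and MHC class II presentation had 3 of 14 (4). Both calls were lost (adjusted p = 0.256 with an estimated correlation for each). RNA quality transcripts had 0 of 15 called and were lower as a list (adjusted p = 0.00806, and 0.266 with an estimated correlation). Osbpl3 (5.66 ± 0.36), the calcium pump Atp2b4 (4.89 ± 0.45) and Ppp1r3fos (4.79 ± 0.55) led outside the lists, and Ggt5 (−4.097 ± 0.37), Vipr1 (−3.01 ± 0.25) and Hs3st3b1 (−2.78 ± 0.28) were lowest. Of 9712 genes, edgeR called 1233, 647 higher and 586 lower, or 759 and 433 with size factors of DESeq2. The count was 281 without the term for mouse and 538 without mouse 1, where Nr4a3, Tlr1, Nr4a1 and H2-Oa (1.03 ± 0.27) no longer passed, and Ifit3 did not pass without mouse 2.

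Marginal zone B cells differed from other B cells in single genes of several groups. The receptor gene Fcrl5 was 3.27 ± 0.16 higher (edgeR adjusted p = 1.16e-15), and Cd1d1, which presents lipids to NKT cells, 1.40 ± 0.20. Lower were Gpr183, the EBI2 receptor that positions cells in follicles (−1.03 ± 0.13), and the lymph node homing receptor Ccr7 (−0.86 ± 0.17). The IgE receptor Fcer2a, or CD23, was also lower (−1.88 ± 0.20). Of 9712 genes, 798 passed edgeR, 516 higher and 282 lower, or 690 and 227 with size factors of DESeq2. Chemokine and egress receptors had 5 of 24 higher and 6 lower (6 and 6 adjusted over the list alone), with Ccr1 at 3.15 ± 0.32. Integrins and adhesion had 3 and 4 of 29 (3 and 5), with Itgb1 higher (1.59 ± 0.15) and Slamf1 lower (−1.37 ± 0.15). Cytokine and TNF-family receptors had 3 and 5 of 38 (5 and 5), with the chain Csf2rb at 3.04 ± 0.22, Il6st (gp130) at 1.40 ± 0.19 and Il21r at −1.04 ± 0.10. Pattern recognition genes had 5 and 1 of 26 (6 and 1), including the scavenger receptor Cd36 (2.63 ± 0.22) and Ly96, the partner of Tlr4 (1.76 ± 0.21). MHC class II presentation had 2 and 4 of 14 (2 and 4), with Cd86 higher (0.97 ± 0.17) and Ciita (−0.72 ± 0.15) and H2-Ob (−0.75 ± 0.13) lower. Immediate-early genes had 4 of 27 lower and 0 higher (4), among them Klf2 (−0.83 ± 0.22). B-cell and myeloid regulators had 6 and 4 of 26 (6 and 5), with Plac8 at 1.76 ± 0.28 and Bcl6, the factor of germinal centre B cells, at −1.54 ± 0.15. T-cell and NK regulators had 3 and 3 of 27 (3 and 3), with Bach2 (−1.48 ± 0.12) and Satb1 (−1.46 ± 0.13) lower. The antigen-receptor list had 4 and 2 of 22 (5 and 4), with Traf1 at 1.05 ± 0.18, Fc receptors 2 and 2 of 13 (2 and 2), and interferon genes 2 and 0 of 26 (2 and 0), with Isg15 at 1.22 ± 0.28. RNA quality transcripts had 3 of 15 higher (5), the mitochondrial mt-Co1 (0.35 ± 0.10), mt-Co2 (0.31 ± 0.10) and mt-Co3 (0.33 ± 0.11, edgeR adjusted p = 0.0469). Nebl (4.19 ± 0.32), the lipase gene Lipc (3.99 ± 0.31) and the cadherin gene Cdh17 (3.14 ± 0.33) were highest outside the lists, and Gpr146 (−1.46 ± 0.24), Lfng (−1.21 ± 0.21) and Fam69a (−1.14 ± 0.15) lowest. Camera called 0 of 13 lists, the smallest adjusted p being 0.0526 for RNA quality (0.709 with an estimated correlation). The count fell to 102 without the term for mouse and to 315 without centring by library, and was 492 without mouse 1 and 1485 without mouse 2. Without mouse 1, Isg15, Fcgrt (−1.07 ± 0.21), Ier2 (−0.61 ± 0.11), Tagap (−1.23 ± 0.23) and mt-Co3 no longer passed.

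Conventional DC1, which present antigen of dead cells to CD8 T cells, expressed more Irf8, the transcription factor of this lineage, than conventional DC2 (3.94 ± 0.24, edgeR adjusted p = 6.26e-15). Cd36 (4.11 ± 0.42), Tlr11, the sensor of profilin (3.82 ± 0.37), Itgae (3.35 ± 0.74) and Cxcr3 (3.33 ± 0.68) were higher too. Conventional DC2 had more of the lectin gene Clec4a2 (−4.68 ± 0.58 in DC1) and more Itgam, the CD11b chain (−2.90 ± 0.54). Of 9712 genes, 916 passed edgeR, 453 higher and 463 lower in DC1. The interferon list had 12 of 26 lower and 0 higher (17 adjusted over the list alone; camera adjusted p = 1.14e-07, and 0.154 with an estimated correlation). Among its members Ifit3 was 31.4-fold lower (8.49 to 262), Ifit2 12.96-fold lower (4.25 to 64.3) and Rtp4 lower by a log2 fold change of −3.16 ± 0.48. Cytokine and TNF-family receptors had 10 of 38 lower and 2 higher (13 and 2), the camera call that held (adjusted p = 4.55e-05, and 0.0173 with an estimated correlation), with Il21r at −2.01 ± 0.26 and Csf1r, the macrophage growth factor receptor, at −1.70 ± 0.39. Pattern recognition genes had 9 lower and 3 higher of 26 (9 and 3; adjusted p = 5.84e-04, and 0.105 with an estimated correlation). The antigen-receptor list had 6 of 22 lower and 0 higher (7 and 1; adjusted p = 0.00464, and 0.187 with an estimated correlation), with Nfkbiz at −2.21 ± 0.34. Chemokine receptors had 4 lower and 2 higher of 24 (4 and 2), with Gpr183 at −2.69 ± 0.25 and Cx3cr1 at −2.99 ± 0.54. Integrins had 7 and 2 of 29 (8 and 3), and MHC class II presentation 4 and 2 of 14 (4 and 2), with H2-Eb2 lower (−3.57 ± 0.50) and Cd86 higher (1.80 ± 0.24). T-cell and NK regulators had 5 and 2 of 27 (5 and 2), with Klrd1 at −3.19 ± 0.36 and Zeb2 at −2.05 ± 0.36. B-cell and myeloid regulators had 3 and 1 of 26 (7 and 4), with Relb at −3.08 ± 0.25, and immediate-early genes 3 and 1 of 27 (5 and 4), with Klf4 at −2.41 ± 0.45 and Jun at −1.30 ± 0.32. Fc receptors had Fcer1g lower (−2.94 ± 0.43) and Fcrla higher (2.33 ± 0.58). The nuclear RNAs Neat1 (−0.78 ± 0.17) and Malat1 (0.59 ± 0.12) moved apart. Langerin (Cd207) was at least 39.6-fold higher, Fzd1 at least 31.8-fold and Gramd2 at least 20.4-fold. Sirpb1a was at least 22.03-fold lower and Sirpb1b and Lysmd2 at least 14.3-fold each, where the Sirpb1 paralogs could share reads. Traf1 (−1.70 ± 0.21), Gadd45b (−2.33 ± 0.62) and Dusp5 (−1.94 ± 0.44) turned to 0.25, 2.70 and 1.44 without centring by library. Gadd45b and Dusp5 passed edgeR as higher there. The classes held 176 and 379 cells, and the count was 319 without the term for mouse. Without mouse 1 it was 445 and Ly9 (−1.07 ± 0.26), Malat1, Ifit2 and Ifit3 no longer passed, nor did Gadd45b without mouse 2.

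NK cells differed from CD8 T cells in 1760 of 9712 genes by edgeR (741 higher and 1019 lower). The granule protease gene Gzmb was 9.79 ± 0.67 higher, Fcer1g, a signalling chain of activating receptors, 8.46 ± 0.52, and the CD16 gene Fcgr3 4.41 ± 0.37. S1pr5, which carries NK cells out of bone marrow and nodes, rose by 8.12 ± 0.46 and the regulator Zeb2 by 6.91 ± 0.39. Gut receptor Ccr9 was 104-fold lower (28.9 to 862) and Il6ra lower at −3.64 ± 0.26. Integrins and adhesion had 13 of 29 higher and 6 lower (17 and 7 adjusted over the list alone), including Itgam (6.49 ± 0.39), Itgax (6.33 ± 0.27, edgeR adjusted p = 1.56e-20) and Itga2 (6.06 ± 0.53), and the camera call held (adjusted p = 1.06e-07, and 9.23e-04 with an estimated correlation). T-cell and NK regulators had 14 and 5 of 27 (14 and 5; adjusted p = 3.34e-04, and 0.147 with an estimated correlation), among them Klrg1 (7.99 ± 0.61). B-cell and myeloid regulators had 7 and 2 of 26 (7 and 2; adjusted p = 0.00260, and 0.144 with an estimated correlation), with Maf at 4.67 ± 0.38 and Irf8 at 4.43 ± 0.27. RNA quality transcripts had 11 of 15 lower and 1 higher (12 and 1; adjusted p = 6.27e-05, and 0.208 with an estimated correlation), including mt-Nd1 (−0.69 ± 0.14) and mt-Cytb (−0.68 ± 0.11), while Neat1 was higher (1.02 ± 0.16). Chemokine and egress receptors had 7 and 5 of 24 (7 and 6), with Ccr2 at 5.97 ± 0.29. Cytokine and TNF-family receptors had 10 and 11 of 38 (11 and 12), with Kit at 5.18 ± 0.57 and Il18rap at 3.96 ± 0.19. Pattern recognition genes had 5 and 2 of 26 (5 and 3), with Tlr1 at −3.002 ± 0.44. The antigen-receptor list had 3 and 2 of 22 (3 and 2), with the chemokine genes Ccl3 (5.55 ± 0.56) and Ccl4 (4.31 ± 0.54) higher. Immediate-early genes had 5 and 3 of 27 (7 and 3), with Dusp5 at 2.46 ± 0.26 and Egr1 at −1.77 ± 0.62 (edgeR adjusted p = 0.0400). MHC class II presentation had 4 of 14 lower (4), with H2-Oa at −1.33 ± 0.37 and with H2-Ob at −1.21 ± 0.39, which turned to 0.30 with doublets kept. Interferon genes had 4 of 26 lower (3), including Ifi27l2a (−3.36 ± 0.22). Fc receptors had 3 and 1 of 13 (3 and 1). Vegfc was at least 205-fold higher, Aoah 819-fold (139 to 33137) and Ttc39c 655-fold (109 to 26669), while Actn2 was at least 18.3-fold lower, Bdh1 36.0-fold lower (6.44 to 1424) and Ggt1 30.4-fold lower (5.43 to 1202). Size factors of DESeq2 gave 897 higher and 792 lower genes, and the Wald test of DESeq2 moved the median of all genes by 0.119 on the log2 scale. The count was 686 without the term for mouse and 862 without mouse 1, where Hsph1 (−0.81 ± 0.26), Mb21d1 (1.13 ± 0.39), H2-Ob, Egr1 and Ifit1bl1 (−1.97 ± 0.46) no longer passed, and Hsph1 did not pass without mouse 2.

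**Figure D3:**
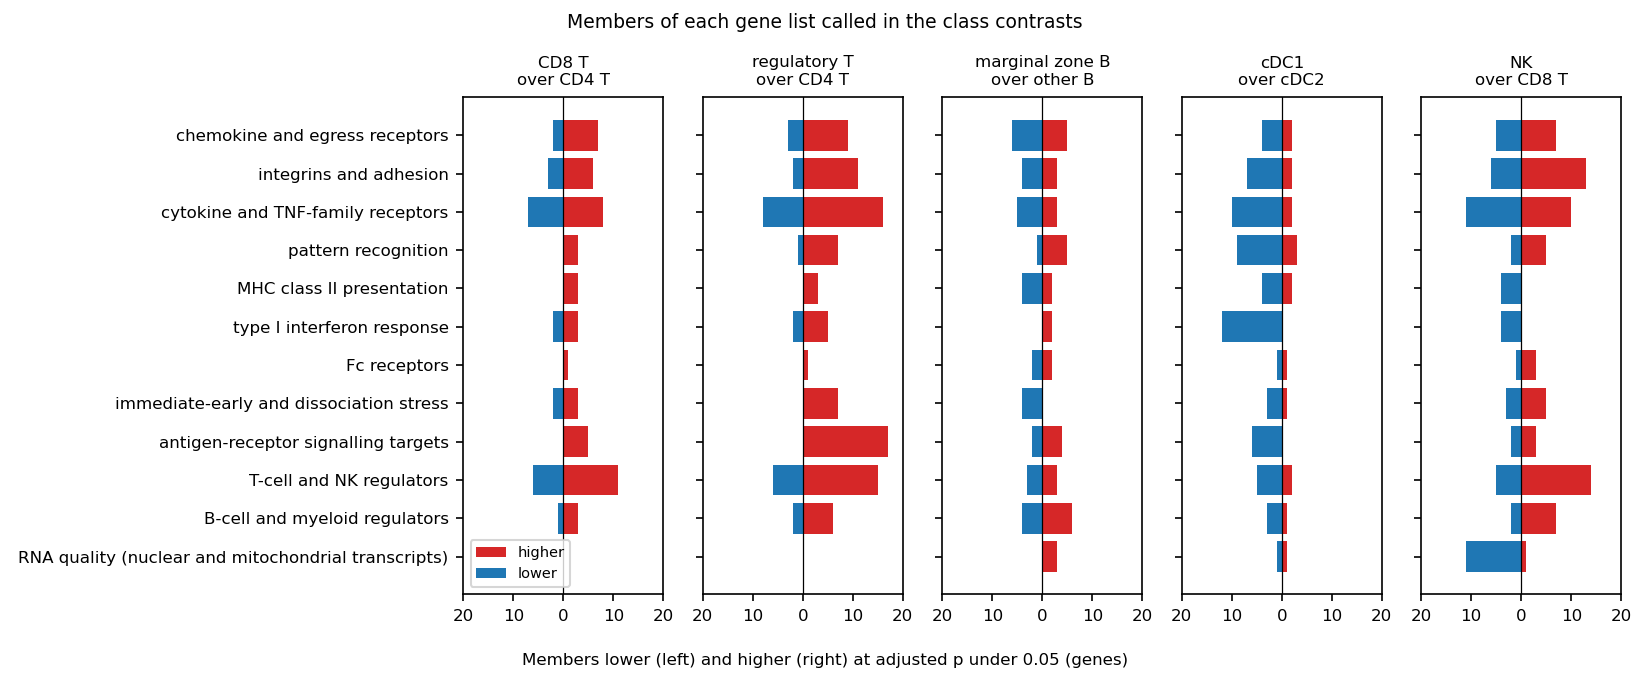
Number of members of each readout list that passed edgeR as higher (right) or lower (left) in the first class of each contrast; the sex-linked list, with 0 calls in every contrast, is left out. Antigen-receptor genes reach 17 higher and 0 lower in regulatory T cells, interferon genes 12 lower and 0 higher in conventional DC1, and RNA quality transcripts 11 lower in NK cells.

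Mouse 2 had more macrophage and neutrophil RNA and less erythroid RNA than mouse 1 with both panels. Over 2-fold ratios in the same direction with both panels were found for 405 genes higher and 300 lower in mouse 2, of 8198 genes at 10 CPM (counts scaled to library totals) or more in 1 mouse. Each side has 1 animal, with the animals processed on separate days and sequenced to different depths, so no test was made. Of the macrophage markers 8 of 10 were over 2-fold higher (median log2 ratio 1.46) and of the neutrophil markers 6 of 7 (1.68). Named genes of these cells were Cxcr2 (2.25), Fpr2 (2.40), Lrg1 (2.31), Mmp8 (2.17), the mannose receptor Mrc1 (2.21) and the iron exporter Slc40a1 (2.07). Erythroid markers had 4 of 5 over 2-fold lower (−1.56), with Hbb-bs at −1.97 and Hbb-bt at −1.96, copies that share reads. Immediate-early genes had 4 over 2-fold lower and 1 higher of 21, Fosb falling furthest (−2.81). RNA quality transcripts had 6 of 15 higher, led by mt-Atp8 (2.22), with a list median of 0.21 and a lowest value of −0.75. The median mitochondrial share per kept cell was lower in mouse 2. It was 5.65% (panel 111) and 5.73% (panel 208), against 6.34% and 6.24% in mouse 1. Eps8l1 (6.21), the peptide transporter Slc15a2 (4.104) and Tsix (2.41), which overlaps Xist on the other strand, were also higher. Ccdc85b (−2.35), Gstp1 (−2.34), Erdr1 (−2.25), Dynlt1f (−2.00), Mid1 (−1.98), Rpl9 (−1.76) and Rpl13 (−1.75) were lower, several of them with paralogs or pseudogenes that could share reads. TMM scaling moved the median of all genes from 0.14 to −0.10 and the split to 189 higher and 678 lower.

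RNA outside called cells, in the 1 library with an unfiltered matrix (panel 111, mouse 2), resembled that of the cells for genes the cells expressed. Barcodes that were not called cells and had 1 to 100 UMIs numbered 690507 and held 6078432 UMIs, or 20.9% of these and the cells together. These UMIs are not a measure of free RNA alone, since barcodes called cells in another library held 541035 UMIs in this matrix. Across 7865 genes at 10 CPM or more in cells, which are not independent, log2 levels outside and in cells had r = 0.978 (rho = 0.967). Levels outside cells were over 2-fold higher for 62 of these genes and over 2-fold lower for 14, a count that leaves out genes rare in cells, such as Rag1 (2.04 CPM in cells and 211 outside). Higher genes included cycling markers, with a list median of 2.22 and values of 2.95 for Nusap1, 2.24 for Stmn1, 2.22 for Hist1h1b and 2.20 for Top2a. Erythroid markers had a median of 1.30 (Hbb-bs 1.81) and T-cell markers 0.71. T-cell markers ran from 10065 CPM in barcodes of 6 to 20 UMIs to 2120 in those of 51 to 100, as genes of immature thymocytes ran from 3162 to 106. B-cell markers (−0.44), neutrophil markers (−0.50) and conventional DC1 markers (−0.59) lay below the cells, as did Cd40lg (−1.68). With barcodes of 1 to 20 UMIs alone, 224 genes were higher and 229 lower.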

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

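All tests of explanations in this part were chosen after the results had been seen, and no biological explanation was tested, since the design gives none for these patterns.

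The ratio between the 2 hashtags should be the same with either antibody panel, yet 2675 tests by class passed the edgeR test of a difference between panels. Exchanged names in 1 panel are a candidate explanation: with the names exchanged in 1 panel, the mean difference between panels over 20 classes fell from 52.1 to 2.94 percentage points, below the differences between mice (7.99 and 6.65). Wrong names in weakly marked cells are argued against, since with a minimum of 50 hashtag UMIs 19 of the 20 classes still lay on opposite sides. Which panel would carry the exchanged names was not tested, although marginal zone B cells, which reside in the spleen, carried the name spleen with panel 208. Any other difference in staining between the panels stays open.

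Barcodes of panel 111 and mouse 2 that were called cells in no library held 3350 UMIs of 7 genes of immature thymocytes, a signal outside the compared cells (510 CPM, against 10.9 CPM in called cells). Such thymocytes may be a source, as a hypothesis: barcodes of 1 to 100 UMIs had 103-fold more Rag1 than cells, 128-fold more Arpp21 and 43.9-fold more Dntt, and all 7 genes were over 2-fold higher. Free RNA of 1 source is argued against, since the list differed 29.9-fold between bins of UMIs, from 3162 CPM (3005 to 3326) at 6 to 20 UMIs to 106 CPM (95.2 to 117) at 51 to 100 UMIs, while B-cell markers differed 3.16-fold. Barcodes of cells of the other libraries held a median of 14 UMIs here, against 0 at barcodes of no library, so UMIs do carry over between libraries in this matrix. By library the medians were 12 (panel 111, mouse 1), 15 (panel 208, mouse 1) and 16 (panel 208, mouse 2). These lie within the bin of 6 to 20 UMIs, where the thymocyte list was highest. Carry-over from a thymus library cannot be told apart from thymocytes in the suspension, because no thymus library is named among the samples.

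Cluster 14 held 676 of its 695 cells (97.3%, 95.8% to 98.3%) in the library of panel 208 and mouse 2, 8.06% (7.49% to 8.66%) of that library, in no class the report compares. Its CD45 antibody level was 3.67% of that of the other cells of the library while isotype controls stood at 75.6%, and 96.6% (94.9% to 97.8%) carried no hashtag against 0.415% (0.284% to 0.585%). Droplets with free RNA and free antibody but no cell may account for it. Across genes its RNA had r = 0.968 with that of its library and 0.960 with RNA outside called cells. The latter was measured in another library, the only one with an unfiltered matrix. There 52316 barcodes of no library's cells held 51 to 100 UMIs, far below the median of 1231 in cluster 14. The depth of empty droplets in the library of panel 208 and mouse 2 is not known, so depth cannot decide this. Pairs of cells in 1 droplet are argued against, since the median UMIs of cluster 14 were 0.556 of those of the other cells (1231 against 2214). B-cell and T-cell markers occurred together in 87.9% of its cells thinned to 1231 UMIs (89.8% unthinned), against 18.4% (32.4% unthinned) of the others, with 340 and 7263 cells deep enough.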

How the results depend on the processing

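Alternatives that omit cells with both hashtags or cluster 14, those of the hashtag comparison and all antibody tests were chosen after the data had been seen. The mouse term set the panel comparison: with the replicate block edgeR called 52 genes in whole libraries and 135 tests by class, against 0 without it. For antibodies the block left 1 call between panels in place of 3, and without it the class contrasts gave 15 (CD8 T), 21 (regulatory T), 14 (marginal zone B), 27 (conventional DC1) and 30 calls (NK). Without a filter on low counts 83 tests by class passed. Leaving out 1 library gave 0 to 1 genes in whole libraries and 38 to 62 tests by class. DESeq2, its size factors, thinning, 10% mitochondrial UMIs, doublets kept, the combined matrices and omission of cells with both hashtags kept both counts at 0, as omission of cluster 14 did for whole libraries, where alone it was run. In the class contrasts no replicate block gave 124 (CD8 over CD4 T), 281 (regulatory over CD4 T), 102 (marginal zone over other B), 319 (conventional DC1 over DC2) and 686 genes (NK over CD8 T). Sums per library with library as block gave 1488 for CD8 over CD4 T and 1389 for marginal zone B, and the 2 classes alone 3055, 2109 for regulatory T and 2399 for marginal zone B. No centring by library gave 315 for marginal zone B. Leaving out a mouse gave 496 to 1850, 538 to 1679, 492 to 1485, 445 to 915 and 862 to 1723 genes in the order above, with fewer without mouse 1 in each contrast. These fits, like the 2 classes alone, used libraries as units. With a mouse left out these are 2 stainings of 1 animal. At Leiden resolution 1.0 no class of conventional DC1, conventional DC2, interferon-high T, cycling T or T cluster 29 was found, so the DC contrast gave no value. With doublets kept no cycling T class was found. Of 2184 values of the 186 genes chosen by the rule under alternatives, 2017 kept direction and call, 163 kept direction and lost the call and 4 reversed. The 2017 include 184 from sums per library and 186 from the 2 classes alone. Those fits take the 2 stainings of a mouse as separate units. A gain was not possible, since the rule takes only genes called in the main fit. The lost calls numbered 68 without the block, 26 without centring, 21 with DESeq2 and 21 without mouse 1. The reversed values were 0.25 (Traf1), 2.70 (Gadd45b) and 1.44 (Dusp5) for conventional DC1 over DC2 without centring by library, and 0.30 (H2-Ob) for NK over CD8 T with doublets kept. Gadd45b and Dusp5 passed edgeR in the reversed direction (adjusted p = 1.69e-05 and 0.00648). The hashtag comparison gave 0 tests without a replicate block, 1 with DESeq2, 953 in panel 208 and 1043 in panel 111, and 6 to 7 without 1 mouse. RNA outside called cells at 1 to 20 UMIs differed over 2-fold for 453 genes in place of 76. Of the 24 class shares, resolution 1.0 and doublets kept each moved 12 by over 1 SD and 10% mitochondrial UMIs moved 3. The share of cells in named classes was 97.8% and stayed within 1 SD. Mouse 2 held 22989994 and 23281099 UMIs against 57757488 and 56960371 for mouse 1, and simulated 2-fold changes were recovered for 30.3% of genes in conventional DC and 37.9% in NK cells, so changes of that size were often missed there. For every change of a count or call given here the cause was not tested, except that leaving out a mouse also removes samples.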

Other observations

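All antibody tests in this part were chosen after the data had been seen, and classes were named from RNA, so proteins of genes used for naming (CD25, GITR, XCR1, CLEC9A, SIRPa, MGL1, NK1.1, CD8a, CD24, CD43, CD5, Ly-6C) are not independent of the classes. Of the 208 antibodies 110 had at least 1000 UMIs in each of the 4 libraries. The highest isotype control reached 41.0 UMIs per cell in a class with panel 208, and 64 of 199 antibodies exceeded that level in at least 1 class. Antibodies below it, such as CD25, PD-1, CD122 and CXCR3, may include unspecific binding. Regulatory T cells bore more CD25, the high-affinity IL-2 receptor chain, than CD4 T cells (log2 fold change 3.93 ± 0.25 SE, n = 2 mice), more Nrp1 (2.89 ± 0.12), GITR (2.52 ± 0.16), the ectoenzyme CD73 (2.36 ± 0.20), ICOS (1.5 ± 0.16) and PD-1 (0.47 ± 0.09), and less CD127, the IL-7 receptor (−1.05 ± 0.13). In this contrast 21 antibodies were higher and 5 lower by edgeR. CD8 T cells had 9 higher and 7 lower, with CD103 (2.00 ± 0.21), CXCR3 (1.36 ± 0.15) and CD122 (0.59 ± 0.10) higher, like their genes Itgae, Cxcr3 and Il2rb, and with Sca-1 lower (−1.96 ± 0.39). The Ly-6C antibody was also higher (2.10 ± 0.33), while RNA of Ly6c1 was lower in the same contrast. Marginal zone B cells had 15 higher and 4 lower, with Sca-1 (1.70 ± 0.39), CD43 (1.26 ± 0.16), CD86 (1.12 ± 0.20) and Ep-CAM (0.93 ± 0.20) higher and with CD23 (−1.33 ± 0.20) lower.

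Conventional DC1 had 21 antibodies higher and 19 lower than DC2. CD8a (3.56 ± 0.34), XCR1 (3.15 ± 0.14), CLEC9A (1.88 ± 0.09), CD24 (1.78 ± 0.27) and Tim-3 (1.32 ± 0.09) were higher, and MGL1 (−1.80 ± 0.20), SIRPa (−1.70 ± 0.14) and the adhesion protein ESAM (−1.39 ± 0.17) lower. NK cells had 14 higher and 18 lower than CD8 T cells, or 20 and 14 with size factors of DESeq2 and 44 and 12 without scaling factors. NK1.1 (4.26 ± 0.15), CD29 (3.60 ± 0.26), B220 (2.19 ± 0.23), CD11c (1.93 ± 0.28) and CD122 (1.34 ± 0.10) were higher and CD5 (−3.22 ± 0.35), the TCR beta chain (−2.50 ± 0.22) and CD103 (−2.02 ± 0.22) lower. Over the 5 contrasts, the gene and its antibody were both called 50 times, with the same sign in 50. Genes used for clustering or naming had no RNA test and are not in this count. Of the 14 (CD8 T), 25 (regulatory T), 17 (marginal zone B), 16 (conventional DC1) and 22 (NK) genes called in RNA among 50 with an antibody, 7, 14, 10, 7 and 12 were called as protein. Fold changes of RNA and protein had r from 0.303 to 0.639 across these genes, which are not independent. Without mouse 1 the counts of called antibodies were 9 for CD8 T, 10 for regulatory T, 8 for marginal zone B, 20 for conventional DC1 and 26 for NK cells.

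Between panels edgeR called 3 of the 110 shared antibodies, all higher with panel 208. They were SiglecH (1.42 ± 0.20, adjusted p = 8.06e-10), CD206 (0.89 ± 0.20, adjusted p = 6.19e-04) and CD370, which is CLEC9A (0.66 ± 0.20, adjusted p = 0.0454). In UMIs per cell SiglecH stood at 6.12 against 2.93 in mouse 1 and 5.94 against 2.90 in mouse 2, CD206 at 5.79 against 4.85 and 7.15 against 4.22, and CLEC9A at 2.77 against 2.55 and 3.33 against 2.49. Uncalled antibodies against alleles that C57/BL6 mice lack lay higher as well (CD90.1 at 0.57, CD45.1 at 0.51), so a shift of weak antibodies is not excluded for CD206 and CLEC9A. The sums also include the 676 cells of cluster 14 in panel 208 of mouse 2, and no antibody test left these out. With mouse as a term 1 antibody passed, DESeq2 called 22 (14 higher, 8 lower), and leaving out the panel 111 library of mouse 2 gave 1. Of the other antibodies of panel 208, CD49f held 123 and 49 UMIs in the libraries of that panel and 141 and 111 in those of panel 111, so 207 reached the minimum of 1000 UMIs there. Isotype controls had a median of 23 UMIs per cell in both libraries of panel 208.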
